A study of Drosophila melanogaster with 3 samples.

How the data were processed

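Binding of GFP-tagged Bdp1 was measured by ChIP-seq in 3 biological replicates of whole embryos aged 0 to 24 h, with chromatin sheared by sonication to 200 to 800 bp, per the labels. All 3 samples form 1 group, as the labels give them. P-values over peaks or genes describe these lists, not a spread between embryos.

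The authors deposited 10 peak lists in narrowPeak format, 5 for each of 2 builds, dm6 and dm3. For each replicate and for the pooled replicates there is a relaxed list, meant as input for the irreproducible discovery rate (IDR) procedure, in which peaks and background stand together. A further list holds the optimal IDR-thresholded peaks, made by the authors from all 3 replicates and the pooled list. The relaxed lists were called against a control alignment, per the text that the authors deposited with the files. The aligner, the peak caller, the filters and the IDR threshold are not given in the sources used here. The value used is the peak signal (signalValue) as the authors deposited it. Its scale between lists is not stated, so signals were compared only within a list, and values of separate replicates were averaged only after division by the median signal of the optimal peaks in that replicate, or as ranks. That division was not part of the plan and was chosen after the data were examined; ranks within a replicate were planned. The number of per-sample columns left without a sample was 0. On both builds the optimal peaks were exactly the strongest peaks of the pooled relaxed list, and 25 of the optimal dm6 peaks share the interval of another with a different summit.

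Coordinates are 1-based on dm6. Genes came from the Ensembl release 115 annotation of BDGP 6.54 and sequence from the matching NCBI assembly, on chromosomes 2L, 2R, 3L, 3R, 4, X and Y. The dm6 lists hold no peak on the mitochondrial genome or on unplaced sequence, so the 22 mitochondrial tRNA genes and the 14 rRNA genes elsewhere were not evaluated. The dm3 lists served for counts, widths and replicate agreement, and no coordinate was converted.

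A gene was counted as occupied when an optimal peak overlapped by at least 1 bp the window of 100 bp on each side of the 5' end of any of its transcripts. Gene classes were compared with protein-coding genes, tRNA families of at least 3 genes with all other nuclear tRNA genes, and 14 lists of protein-coding genes with all other protein-coding genes. Each comparison used a two-sided Fisher's exact test with Benjamini-Hochberg adjustment within its family and a threshold of 0.05. Before the lists were tested, peaks at Pol III genes were left out. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error over genes or peaks only. The peaks were also placed at random within their chromosomes 1000 times, and 100 times for each directed pair of replicates. For values per replicate, the 3206 strongest relaxed peaks of each replicate were used, as many as there are optimal peaks. For a named peak, the highest signal among the replicate's relaxed peaks that contain its summit was taken. Where 1 replicate had no such peak no mean is given. Signals at Pol III genes and elsewhere were compared by a two-sided permutation test of the difference in median log2 signal, with 100000 permutations in each replicate. Summit positions used tRNA genes with no other Pol III gene within 1000 bp. Peaks per chromosome were tested against assembled length with exact binomial tests. Peaks were assigned to features in the order Pol III gene 5' end, protein-coding 5' end, other 5' end, exon, intron and intergenic, the last 3 by the summit.

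The genes to be named were set by a rule before the data were examined. So were the gene lists, the alternative settings and the tests, except those that the closing part names as chosen afterwards. The rule took each U6, U6atac, 7SK, 7SL, RNase P and RNase MRP gene, the 5S genes as a group, the 10 tRNA genes of highest mean percentile rank over the replicates, up to 10 tRNA genes without a peak in genome order, the 10 highest peaks outside Pol III genes, members with a peak of lists of up to 20 genes, the 4 highest of longer lists, and Bdp1. Families of tRNA genes named beyond the highest and lowest share were chosen after their values were seen.

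For the closing part, words of 32 bases within 200 bp of a 5' end were counted as unique when found once in the genome. Matches to tRNA genes in blastn needed at least 30 bp and an E of at most 0.001. On either strand, 4 promoter motifs were searched within 100 bp of the outermost 5' end of each gene.

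The alternatives were the 1603 optimal peaks of highest signal, peaks found among the strongest of at least 2 of the 3 replicates, each replicate left out in turn, a summit within 250 bp of the 5' end, windows of 500 bp, Pol III peaks kept in the list tests, other numbers of peaks and other overlap rules for replicate agreement, the dm3 lists, all tRNA genes or the optimal summits for the summit position, expected numbers from gene content, and a B box with no mismatch.

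Scripts were tested on simulated data. With peaks placed at 200 of 13968 protein-coding genes and at 1000 random positions, 100% of the genes given a peak were called and 0.705% of the others. A signal difference of 3 on the log2 scale was recovered as 2.83, and an overlap of 60% as 60%. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, samtools 1.23.1 and blastn 2.17.0.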

Results

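Bdp1 is a subunit of TFIIIB, the factor that places RNA polymerase III (Pol III) on its promoters. Pol III makes tRNA, 5S rRNA, U6 snRNA and other short RNAs. Its binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole *Drosophila melanogaster* embryos of 0 to 24 h, of both sexes. The embryos came from a transgenic line that makes Bdp1 (CG9305) with a C-terminal green fluorescent protein (GFP), and the antibody was raised against GFP. There were 3 biological replicates in 1 group. With no second group, the design asks where Bdp1-GFP was found, how closely the replicates matched, and whether Pol III genes carried more and stronger peaks than other genes. The authors' optimal set, made from all 3 replicates, held 3206 peaks on build dm6, with a median width of 396 bp. Together they covered 1187 kb, or 0.863% of the 7 assembled chromosomes. Each replicate also had a relaxed list of 30000 peaks that mixes binding sites with background. The lists carry no read totals, so the sequencing depth behind a peak is unknown here.

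The replicates shared most of their strongest peaks. Of the 3206 strongest peaks of a replicate, 68.9% ± 2.31 (SD over 6 directed pairs of the 3 replicates) overlapped by at least 1 bp one of the 3206 strongest of another. The lowest share was 65.5% and the highest 71.5%. Random placement of the same peaks within their chromosomes gave 1.84% ± 0.0635. Across the overlapping peaks, which are not independent replicates, Spearman's rho of the peak signal lay between 0.679 and 0.738. Of 236 optimal peaks at Pol III genes, 230 (97.5%) overlapped a strongest peak in all 3 replicates, against 1580 of the 2970 others (53.2%), most of which were weaker. No interval was identical in any pair of replicates.

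Nuclear tRNA genes carried Bdp1-GFP almost throughout. An optimal peak overlapped the 200 bp around the 5' end (100 bp on each side) of 269 of 290 tRNA genes, or 92.8% (95% exact Clopper-Pearson interval 89.1 to 95.5%). In the separate replicates the share was 90.7% ± 1.24 (SD, n = 3). Neighbouring genes can be counted through 1 shared peak: 236 optimal peaks lay at the 275 Pol III genes that had one. Among protein-coding genes 1913 of 13968 (13.7%) had a peak, and random placement of the peaks reached 1.40% of tRNA genes on average and 4.83% at most. The difference from protein-coding genes had an adjusted p of 6.08e-195 (two-sided Fisher's exact test, Benjamini-Hochberg over 13 gene classes), and the share was higher in tRNA genes in 3 of 3 replicates. All 3 U6 snRNA genes, which encode the RNA at the catalytic centre of the spliceosome, had a peak (adjusted p = 0.00558, Fisher's exact test). None of the 96 genes of the 5S rRNA array had one, and none had a relaxed peak in any replicate. The array lies at 19729562 to 19766278 on 2R and its units are near-identical repeats, so this count cannot be read as absence of binding. Outside the Pol III classes, 12% of Pol II-transcribed snRNA genes had a peak (3 of 25, adjusted p = 1, Fisher's exact test). The share was lower than in protein-coding genes for snoRNA and scaRNA genes (4.74%, 13 of 274), miRNA genes (1.54%, 4 of 260) and other non-coding RNA genes (2.58%, 78 of 3021), with adjusted p of 6.80e-06, 2.68e-11 and 1.70e-86 (Fisher's exact test). Among the 1603 strongest optimal peaks the snoRNA and scaRNA call was lost (4.38% against 6.80% of protein-coding genes, adjusted p = 0.206, Fisher's exact test). Windows of 500 bp kept these calls and gave snoRNA and scaRNA genes 11.3%, miRNA genes 3.46% and other non-coding RNA genes 5.86%. A wider window can only raise a share, so these values cannot be set against the 13.7% of protein-coding genes at 100 bp.

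**Figure D1:**
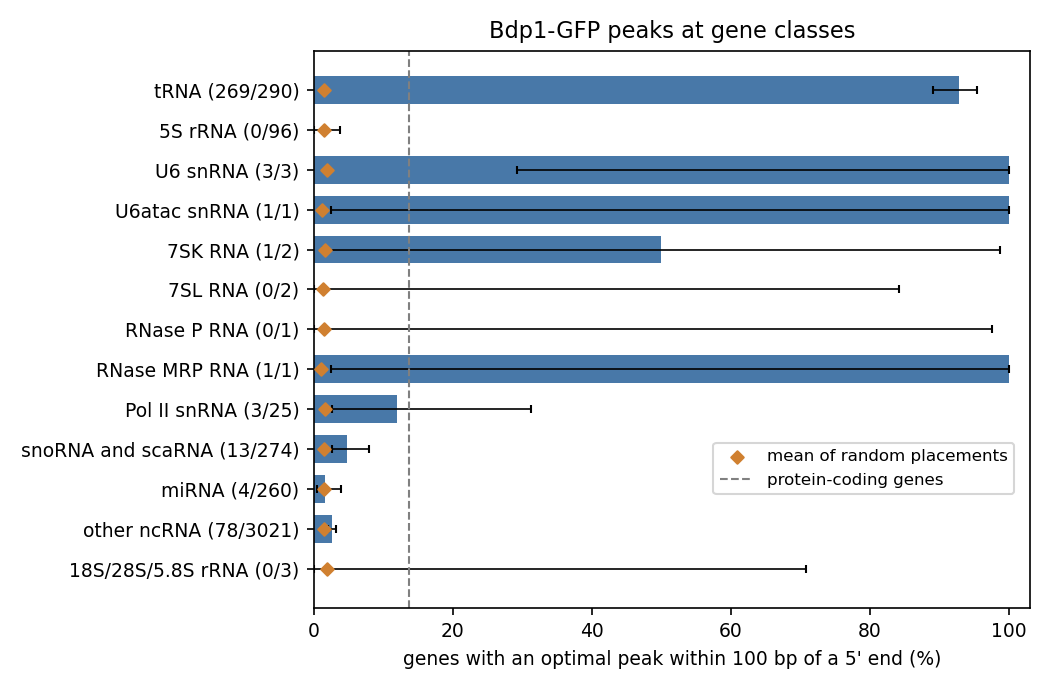
Share of genes of each class with an optimal peak within 100 bp of a 5' end, in percent, with 95% exact intervals over genes; diamonds give the mean of 1000 random placements and the dashed line the 13.7% of protein-coding genes. The bar of the 290 tRNA genes reaches 92.8%, while that of the 96 5S rRNA genes stays at 0.

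The other Pol III genes differed from one another. The U6 genes lie together on 3R. snRNA:U6:96Ac (24557215 to 24557321) sat under the peak of pooled rank 3, at 24556491 to 24557426, whose signal was 73.5 ± 9.28 times (SD, n = 3) the median of the optimal peaks in the same replicate. That peak also reached the window of snRNA:U6:96Ab (24556692 to 24556798), but its summit lay 414 bp downstream of the 5' end of that gene, and of the replicates' strongest peaks only that of replicate 1 touched the window. snRNA:U6:96Aa (24556088 to 24556194) had its own peak at 3.71 ± 1.49 times the median. Without replicate 1, 66.7% of the U6 genes had a peak and the class no longer passed the threshold (adjusted p = 0.0583, Fisher's exact test). The same share was reached when the summit had to lie within 250 bp of the 5' end (adjusted p = 0.101, Fisher's exact test), with snRNA:U6:96Ab the gene lost in both. The U6atac, 7SK, 7SL, RNase P and RNase MRP classes hold 1 or 2 genes each, and none passed the test. snRNA:7SKa (3R, 7474553 to 7474996), a regulator RNA of Pol II elongation, had a peak of 26.5 ± 4.47 times the median. RNaseMRP:RNA (3R, 23730048 to 23730429), the RNA of a pre-rRNA processing enzyme, had one of 19.9 ± 4.20 times, and snRNA:U6atac (2L, 8389724 to 8389820), of the minor spliceosome, one of 2.31 ± 0.368 times. No optimal peak reached snRNA:7SKb (3R, 23432869 to 23433272), RNaseP:RNA (3R, 31217364 to 31217662), or the pair of genes for the 7SL RNA of the signal recognition particle, 7SLRNA:CR42652 (3R, 6820131 to 6820429) and 7SLRNA:CR32864 (3R, 6822500 to 6822798). RNaseP:RNA did have relaxed peaks, of rank 15365 in replicate 1 and 4214 in replicate 2. It was counted as a Pol III gene by its name. Which polymerase transcribes it in the fly was not examined, so its lack of a peak is not shown to be a gap in Pol III binding. Windows of 500 bp around the 7SL genes reached only the peaks of the neighbouring genes tRNA:Lys-TTT-2-1 and tRNA:Lys-TTT-2-4.

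**Figure D2:**
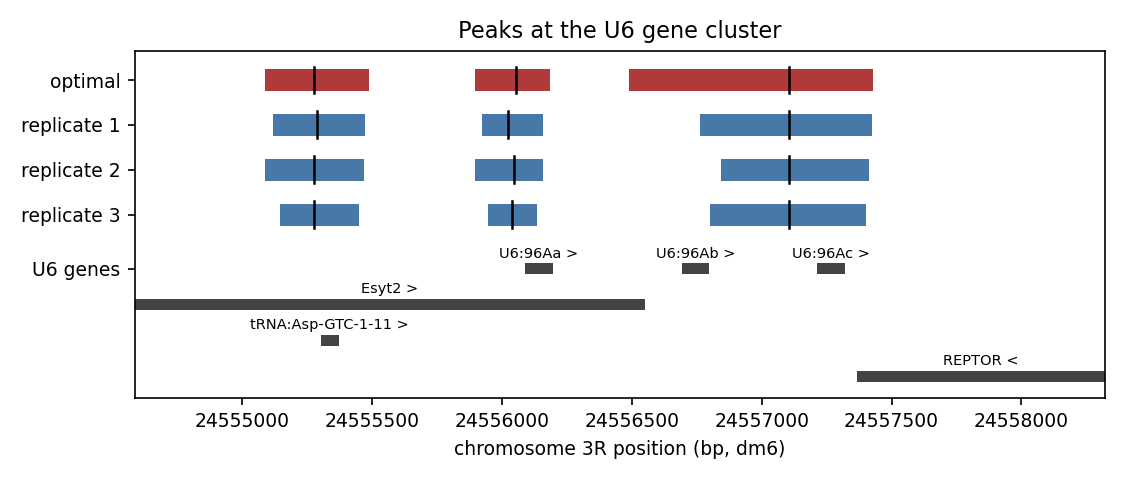
Map of the U6 gene cluster on chromosome 3R of dm6, in bp, with the optimal peaks in red, the strongest peaks of each replicate in blue and a black line at each summit; arrowheads after gene names give the strand. The widest optimal peak, from 24556491 to 24557426, has its summit at 24557106, just upstream of snRNA:U6:96Ac.

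The strongest peak of all 3 replicates stood at tRNA:Thr-AGT-1-4 (FBgn0051282; 3R, 16431940 to 16432013). Its signal was 127 ± 15.3 times the median of the optimal peaks (SD, n = 3). The next tRNA genes were tRNA:iMet-CAT-1-4 and tRNA:iMet-CAT-1-5 (3L, 14673942 to 14674013 and 14674344 to 14674415), a divergent pair of initiator tRNA genes under 1 peak of 77.6 ± 6.32 times the median. A cluster of serine tRNA genes on 3R, tRNA:Ser-GCT-2-4, tRNA:Ser-GCT-1-1 and tRNA:Ser-GCT-2-5, shared a peak at 22396712 to 22397796 of 63.2 ± 6.38 times, although in replicates 2 and 3 it did not reach tRNA:Ser-GCT-2-4. tRNA:Pro-CGG-2-3 (3L, 18618390 to 18618461) ranked 5 in each replicate, at 59.4 ± 3.72 times. The alanine cluster tRNA:Ala-CGC-1-1, tRNA:Ala-CGC-1-2 and tRNA:Ala-CGC-1-3 lay under 1 peak on 2R (25075675 to 25077257) of 53.4 ± 6.71 times, while in each replicate tRNA:Ala-CGC-1-1 had a separate, lower peak. When the summit had to lie within 250 bp of the 5' end, tRNA:Ser-GCT-2-4 and tRNA:Ala-CGC-1-3 had no peak. Where genes share a peak, its value cannot be divided among them.

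tRNA genes without an optimal peak were 21. The first 10 in genome order were tRNA:Arg-TCT-2-1, tRNA:Arg-TCT-3-1, tRNA:Gly-GCC-1-4, tRNA:Gly-GCC-1-7 and tRNA:Leu-TAA-3-1 on 2L, and tRNA:Glu-CTC-3-5, tRNA:Glu-CTC-3-6, tRNA:Glu-CTC-3-7, tRNA:Cys-GCA-2-1 and tRNA:Lys-CTT-1-13 on 3L. Of the 21, 9 had a relaxed peak in at least 1 replicate and 3 in all. tRNA:Arg-TCT-2-1 was one of the latter, with ranks of 3279, 6915 and 5418 in replicates 1, 2 and 3. The others were tRNA:Leu-CAG-1-5, with ranks of 46, 29186 and 2376, and tRNA:Ser-GCT-2-1, with 2986, 3036 and 28935. Some tRNA genes without an optimal peak thus had a peak among the 3206 strongest of a replicate. With windows of 500 bp, tRNA:Gly-GCC-1-4, tRNA:Gly-GCC-1-7, tRNA:Glu-CTC-3-5, tRNA:Glu-CTC-3-6 and tRNA:Lys-CTT-1-13 reached a peak, in each case that of a neighbouring tRNA gene. tRNA:Gly-GCC-1-4 had one in its 100 bp window among the peaks found in at least 2 of the 3 replicates.

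Most amino acid families of tRNA genes were occupied throughout. In 12 of the 21 families with at least 3 genes, among them alanine (17 genes), threonine (17), proline (17), valine (15) and the initiator methionine genes (6), every gene had a peak. Clustered genes could be counted through a neighbour's peak, as with tRNA:Ala-CGC-1-3. The lowest share was that of cysteine, with 5 of 7 genes (71.4%, 95% exact interval 29.0 to 96.3%). Lysine followed with 15 of 19 (78.9%, interval 54.4 to 93.9%). Of the 21 families 0 passed an adjusted p of 0.05 (Fisher's exact test against all other nuclear tRNA genes, Benjamini-Hochberg). With 92.8% of all tRNA genes occupied, a complete family could not have passed, and a small one only with many of its genes unoccupied. The absence of a call therefore does not show that the families are alike. Lysine alone had an unadjusted p below 0.05, at 0.0386 (Fisher's exact test), and an adjusted p of 0.81. The single selenocysteine gene, which was too few to test, had a peak.

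Peaks at Pol III genes were much stronger than the rest. Their median signal exceeded that of the other optimal peaks 8.52-fold in replicate 1, 8.25-fold in replicate 2 and 6.79-fold in replicate 3. On the log2 scale the difference was 2.97 ± 0.18 (SD, n = 3). In each replicate the permutation p was 1e-05, the smallest that 100000 permutations can give (two-sided, over peaks, which are not independent replicates). Of the 20 strongest optimal peaks 17 lay at Pol III genes, and of the 100 strongest 88. The exceptions were led by a peak on 2R (9541479 to 9542041, intergenic, 5187 bp downstream of the 5' end of CG1888), at 50.6 ± 9.49 times the median of the optimal peaks.

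**Figure D3:**
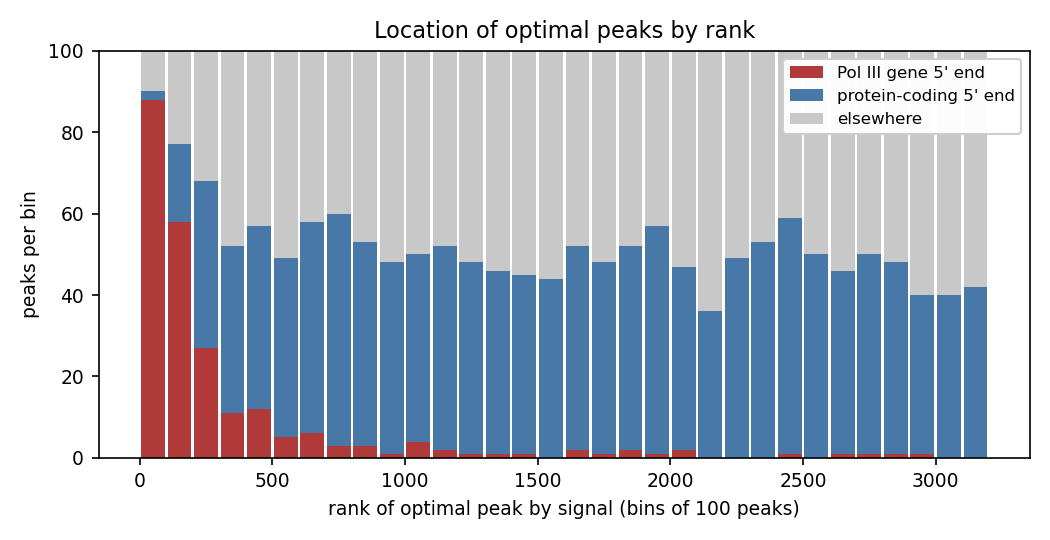
Number of optimal peaks per bin of 100 ranks by signal (rank 1 is the strongest) at Pol III gene 5' ends, at protein-coding 5' ends and elsewhere; the last, incomplete bin is left out. Pol III genes take 88 of the 100 strongest peaks and 58 of the next 100.

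Several of the strongest peaks outside annotated Pol III genes lay beside snoRNA genes, whose RNAs guide the modification of rRNA. A peak 163 bp upstream of snoRNA:Psi18S-176 (2R, 23839844 to 23840508) was 40.8 ± 7.47 times the median, one 232 bp upstream of snoRNA:Psi28S-3342 (X, 5524409 to 5524917) 31.4 ± 5.74 times, and one 141 bp upstream of snoRNA:Or-aca4 (2R, 17616346 to 17616919) 26.1 ± 2.73 times. One 159 bp upstream of snoRNA:CG31191-a (3R, 20912790 to 20913240, within CG31191) was 14.9 ± 1.90 times. The others among the 10 highest by mean rank were at lncRNA:CR43604 inside dachs (2L, 8485491 to 8485976; 28.2 ± 1.5 times), sncRNA:CR43701 inside stet (3L, 1488473 to 1488931; 18.8 ± 0.808 times; the peak also reached the 5' end of snoRNA:Psi28S-2622), an intron of CG42588 (3L, 12815679 to 12816085; 17.1 ± 1.32 times), an intergenic site 1213 bp from the 5' end of CG34435 (X, 5613009 to 5613502; 11.8 ± 1.52 times) and the 5' end of CG14100 (3L, 19590445 to 19590792; 11.01 ± 1.30 times). The Bdp1 gene itself (FBgn0032512; 2L, 13371427 to 13373890) had a peak at its 5' end, at 13373779 to 13374193, of 6.61 ± 0.251 times.

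At tRNA genes the peaks lay just upstream of the gene. Among tRNA genes with no other Pol III gene within 1000 bp, the median summit stood 30.5 bp upstream of the 5' end in replicate 1 (90 genes), 29 bp in replicate 2 (92 genes) and 28 bp in replicate 3 (89 genes). The mean of the medians was -29.2 ± 1.26 bp (SD, n = 3, upstream negative). Upstream summits outnumbered downstream ones by 82 to 7, 82 to 9 and 78 to 10 (exact binomial tests, p = 2.43e-17, 7.09e-16 and 3.33e-14). The summit was 31 bp upstream at snRNA:U6atac, 23 bp at snRNA:7SKa, 26 bp at RNaseMRP:RNA and 34 bp at snRNA:U6:96Aa, and it was 109 bp upstream at snRNA:U6:96Ac.

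**Figure D4:**
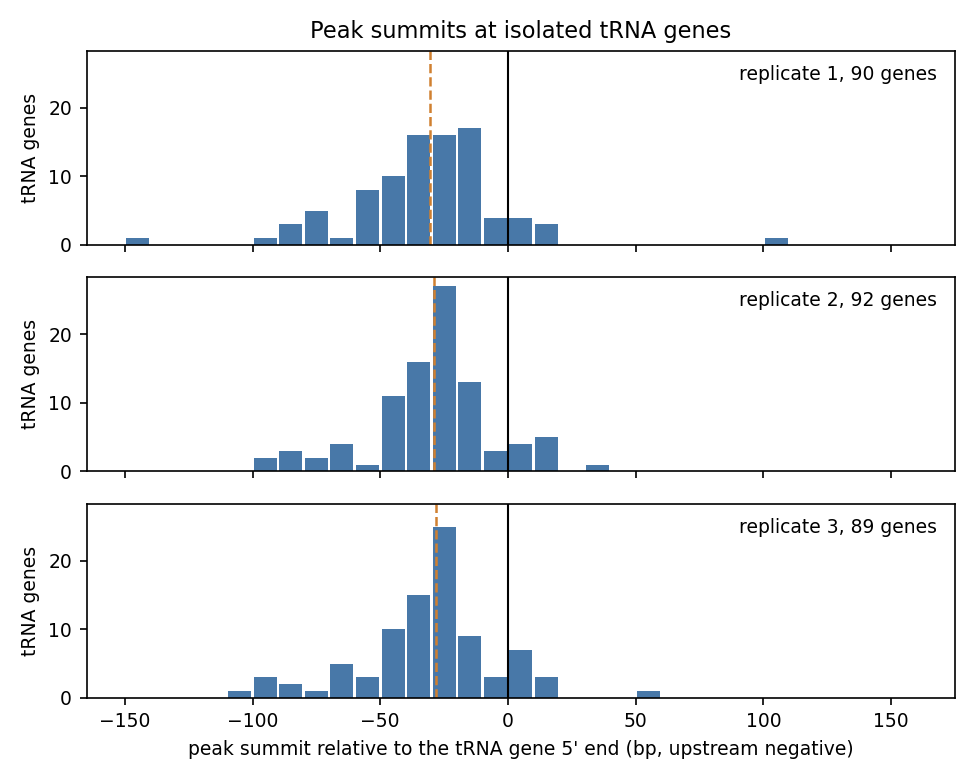
Number of isolated tRNA genes by the distance of the peak summit from the gene's 5' end, in bins of 10 bp, for each replicate; upstream is negative, the black line marks the 5' end and the dashed line the median. The medians lie 28 to 30.5 bp upstream.

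Outside Pol III genes, Bdp1-GFP peaks were frequent at genes of the protein synthesis machinery. Peaks at Pol III genes were first set aside, which left 1899 of 13968 protein-coding genes (13.6%) with a peak at a 5' end. Of 88 genes for cytoplasmic ribosomal proteins 55 had a peak (62.5%, 95% exact interval 51.5 to 72.6%; 59.8% ± 7.57 in the separate replicates, SD, n = 3), against 13.3% of the other protein-coding genes. The adjusted p was 2.59e-25 (Fisher's exact test, Benjamini-Hochberg over 14 lists). RpS27 (4.18 ± 0.949 times the median of the optimal peaks), RpL7 (4.05 ± 1.5), RpL17 (2.93 ± 0.372) and RpL34b (2.89 ± 0.289) ranked highest. Of 20 aminoacyl-tRNA synthetase genes, whose products charge tRNAs, 8 had a peak (40%, adjusted p = 0.00633, Fisher's exact test). They were SerRS (2.44 ± 0.495 times), GluProRS (1.41 ± 0.430), ThrRS (1.12 ± 0.158), IleRS (1.08 ± 0.320), AsnRS (0.892 ± 0.352), AspRS (0.884 ± 0.0479), beta-PheRS (0.705 ± 0.0834) and alpha-PheRS. The peaks at AsnRS, AspRS and beta-PheRS were thus below the median, and alpha-PheRS lacked a value in 1 replicate. Of 52 translation factor genes 17 had one (32.7%, adjusted p = 0.00118, Fisher's exact test), led by eIF6 (4.39 ± 0.815 times), eEF1gamma (2.45 ± 0.618), eIF3c (2.16 ± 0.446) and eEF5 (1.38 ± 0.558). Of 73 mitochondrial ribosomal protein genes 21 had one (28.8%, adjusted p = 0.00225, Fisher's exact test), led by mRpS10 (6.27 ± 0.855 times), mRpL41 (6.11 ± 0.969), mRpL23 (3.93 ± 1.11) and mRpL34 (1.36 ± 0.360). Smaller peak sets lowered the share of all protein-coding genes as well, and the mitochondrial list lost its call in 3 of them. It had 16.4% against 9.63% of the other genes without replicate 1 (2115 peaks, odds ratio 1.85 instead of 2.58, adjusted p = 0.139), 16.4% against 8.45% without replicate 3 (1977 peaks, odds ratio 2.13, adjusted p = 0.0622) and 13.7% against 6.65% among the 1603 strongest peaks (odds ratio 2.23, adjusted p = 0.0681, all by Fisher's exact test). Among the 1603 the translation factors lost theirs too, with 13.5% against 6.66% (odds ratio 2.18 instead of 3.11, adjusted p = 0.147), while 25% of the synthetase genes had a peak (adjusted p = 0.0247, Fisher's exact test), and without replicate 3 the translation factors stood at 21.2% (adjusted p = 0.013).

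Housekeeping genes that are highly transcribed had peaks at 7 of 14 5' ends (50%, adjusted p = 0.00283, Fisher's exact test). They were the chaperone genes Hsp83 (2.30 ± 0.689 times) and Hsc70-4 (1.09 ± 0.202), the elongation factor genes eEF1alpha1 (1.25 ± 0.300) and eEF2 (0.971 ± 0.494), the tubulin gene alphaTub84B (1.05 ± 0.663), the glycolysis gene Gapdh2 and the ubiquitin gene Ubi-p63E. Both elongation factor genes also belong to the translation factor list, so the calls of these lists are not independent. Without replicate 3 the share was 28.6%, against 8.47% of the other protein-coding genes, and the call was lost (odds ratio 4.32 instead of 6.38, adjusted p = 0.0605, Fisher's exact test). Among 18 genes of the Pol III machinery 5 had a peak (27.8%, adjusted p = 0.135, Fisher's exact test), among them Bdp1, Brf (1.90 ± 0.571 times; another TFIIIB subunit), the polymerase subunit gene Polr3E (0.880 ± 0.514) and La (0.705 ± 0.296; a binder of Pol III transcripts). The nucleolar list (4 of 12, adjusted p = 0.120, Fisher's exact test: Fib, Nopp140, Nnp-1 and NHP2) and the proteasome list (8 of 48, adjusted p = 0.566, with Rpn5, Rpn3, Rpn6 and Rpn8 ranking highest) did not pass the threshold either. Without replicate 1 the Pol III machinery stood at 11.1%, the nucleolar list at 16.7% and the proteasome list at 10.4%, and without replicate 3 at 16.7%, 8.33% and 6.25%. In these smaller sets the share of other protein-coding genes was lower as well, as given above for the mitochondrial and housekeeping lists. Untagged embryos were not analysed here, so background at active promoters was not measured.

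Genes little used in embryos, such as odorant and taste receptor genes and yolk protein genes, rarely had a peak. Of 145 such genes 1 had one (Gr63a, a carbon dioxide receptor gene; 0.690%, adjusted p = 1.88e-07, Fisher's exact test). The other tissue and stage lists did not pass the threshold. Among 30 embryonic patterning genes bcd alone had a peak (3.33%, adjusted p = 0.159), among 12 muscle genes sls, Mef2 and Tm1 (25%, adjusted p = 0.276), among 11 heat shock genes Hsp27 and Hsp26 (18.2%, adjusted p = 0.653) and among 10 neuronal genes none (adjusted p = 0.439, all by Fisher's exact test). In the separate replicates the patterning share was 6.67% ± 3.33, the muscle share 19.4% ± 4.81 and the neuronal share 10% ± 10 (SD, n = 3). None of the 111 replication-dependent histone genes had a peak (adjusted p = 7.81e-07, Fisher's exact test). These lie in near-identical repeats, like the 5S rRNA genes, and their 0 is not a measure of binding.

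**Figure D5:**
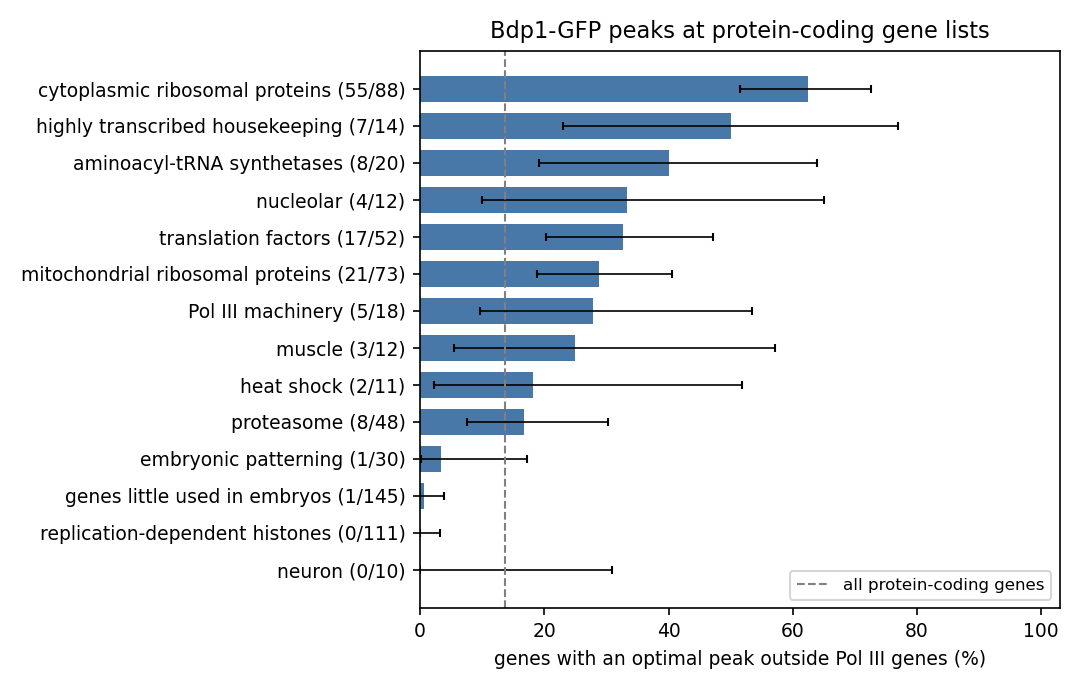
Share of protein-coding genes of each list with an optimal peak outside Pol III genes, in percent, with 95% exact intervals over genes; the dashed line marks the 13.6% of all protein-coding genes. Cytoplasmic ribosomal protein genes stand highest at 62.5%, and replication-dependent histone and neuronal genes are at 0.

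Protein-coding promoters nevertheless held the largest part of the peak set. Of the 3206 peaks 44.8% lay at a protein-coding 5' end (95% exact interval 43.0 to 46.5%), 7.36% at a Pol III gene (6.48 to 8.32%), 1.87% at the 5' end of another gene, 3.59% in other exon sequence, 30.6% in introns and 11.9% between genes. Random placement gave 7.14% at protein-coding 5' ends, 0.140% at Pol III genes, 22.3% in exons, 40.8% in introns and 28.4% between genes. Pol III genes held 26.2% of the 801 strongest peaks (23.2 to 29.4%), 13.9% of the 1603 strongest and 0.624% of the 801 weakest (0.203 to 1.45%). Protein-coding 5' ends held 37.6% of the 801 strongest and 46.3% of the 801 weakest. In the separate replicates the share at Pol III genes was 7.51% ± 0.198 and that at protein-coding 5' ends 44.0% ± 4.996 (SD, n = 3).

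Chromosome 4, which is small and largely heterochromatic, had 5 peaks where 31.4 were expected from its length (0.159 times, adjusted p = 5.18e-08, exact binomial test, Benjamini-Hochberg over 7 chromosomes). The Y chromosome had 0, with 85.5 expected (adjusted p = 3.38e-37, exact binomial test). That expectation rests on length alone. The Y holds 0 of the 290 tRNA genes, and even the relaxed lists held at most 1 peak on it. How much of the Y reads can be placed on was not examined, so its 0 is not a measure of binding. The X chromosome as a whole was near its share, with 529 peaks (0.964 times, adjusted p = 0.435, exact binomial test). Peaks at Pol III genes lie where those genes are: X held 7.203% of them (17 of 236) and 8.28% of the tRNA genes (24 of 290), and 2R 31.4% (74) and 33.8% (98). Chromosome 2L had 598 peaks (1.09 times, adjusted p = 0.0471, exact binomial test), and against its share of annotated genes the ratio was 0.944 and the call was lost (adjusted p = 0.121).

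The internal promoter element of tRNA genes, the B box (GGTTCGANTCC, with at most 1 mismatch on either strand), was no more common at peaks away from annotated Pol III genes than beside them. It was found within 100 bp of the summit of 25 of 2970 such peaks (0.842%, 95% exact interval 0.545 to 1.24%) and in 22 of the same regions shifted by 2000 bp (0.741%, p = 0.77, Fisher's exact test). At the 236 peaks of Pol III genes it was found in 101 (42.8%), against 6 of the shifted regions (2.54%). With no mismatch allowed, 0.168% of the peaks away from Pol III genes had a match (p = 0.219, Fisher's exact test).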

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

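Peaks on sequences outside the chromosome arms were counted in the dm3 relaxed lists, which served above only for counts, widths and replicate agreement. Apart from the control alignment used in the calling, no control sample was analysed here to set a level for them. Their number is above the 3 that a count of 0 allows. The relaxed list of replicate 1 held 80 such peaks, that of replicate 2 held 60, that of replicate 3 held 93 and the pooled list 27. The optimal lists of both builds held none. The largest numbers were on the heterochromatic sequence 3LHet, with 25, 17 and 28 peaks in replicates 1, 2 and 3. The best placed of them all was a peak on the mitochondrial genome, of rank 1161 in replicate 1 and seen in no other replicate. On the dm6 build the Y chromosome held 1 relaxed peak in replicate 1, of rank 21867, and 1 in replicate 3, of rank 11524. No explanation was tested.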

How the results depend on the processing

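No alternative was added after the results were seen. Taking the strongest peaks of the pooled relaxed list returned the optimal set itself and moved nothing. Occupancy of tRNA genes, the signal difference at Pol III genes, the ribosomal protein list, the absence of a call among tRNA families and the B box comparison kept their direction and their side of the threshold under every alternative run for them. Among the 1603 strongest optimal peaks, 13.9% lay at Pol III genes, 5 chromosomes passed the threshold instead of 3, and calls ended for snoRNA and scaRNA genes (4.38%), mitochondrial ribosomal proteins (13.7%) and translation factors (13.5%). Peaks of at least 2 replicates placed 7.07% at Pol III genes. With 1 replicate left out, the share of peaks at Pol III genes was 9.19 to 9.81%, U6 genes occupied 66.7 to 100%, mitochondrial ribosomal proteins 16.4 to 27.4%, highly transcribed housekeeping genes 28.6 to 42.9% and replicate agreement 66.1 to 71.0%. These sets held 1977 to 2123 peaks, since a peak had to be among the strongest of both remaining replicates. The changes therefore cannot be credited to the replicate left out alone, and their cause was not tested further. Requiring a summit within 250 bp left 66.7% of U6 genes, without a call, and 85.2% of tRNA genes in the separate replicates, while windows of 500 bp gave 94.8% of these and placed 54.9% of peaks at protein-coding 5' ends. Replicate agreement was 75.4% for the top 1000 peaks, 47.4% for 5 times as many peaks, 63.03% with 50% reciprocal overlap and 60.6% for summits within 100 bp. The summit position was -31.5 bp over all tRNA genes and -31 bp in the optimal list. Against gene content, chromosome 2L stood at 0.944 instead of 1.09. A further 271 values of the comparisons kept their side of the threshold or moved by less than the spread. For the named Pol III genes, Bdp1 and named peaks elsewhere, 312 values were unchanged, 11 gained and 5 lost a peak; 7 of the gains were neighbouring tRNA genes' peaks reached by windows of 500 bp. Of the 47 named list members, all with an optimal peak, 35 had one among the 1603 strongest peaks, 45 among peaks of at least 2 replicates, 37, 41 and 34 without replicates 1, 2 and 3, 42 with the summit rule and 46 with windows of 500 bp. Shares of the other features moved 9 times, 4 up and 5 down, and 168 values for tRNA families kept their side of the threshold. These counts of unchanged values include the setting that returned the optimal set itself, which could not differ. Many of the family values could not have passed the threshold either, so the counts are no measure of robustness. With the read depth unknown, a missing peak is not shown to be missing binding.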

Other observations

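The tests of patterning genes, of the part of the tRNA genes with mostly repeated sequence, of nearby protein-coding promoters and of the reach of the blastn search were chosen only after the values, or the positions of such peaks, had been seen. The design has 1 group, so no explanation by a difference between groups was tested.

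Promoters with a peak differed in sequence from those without. Within 100 bp of the 5' end, Motif 1 (GGTCACAC), found at broadly active fly promoters, occurred in 10.1% of 1899 protein-coding genes with a peak outside Pol III genes and in 6.21% of the 12069 without (adjusted p = 1.13e-08, Fisher's exact test, Benjamini-Hochberg over 4 motifs). The sequence TATAAAA, that of the TATA box common at regulated promoters, was rarer, at 10.8% against 15.2% (adjusted p = 2.89e-07, Fisher's exact test). GAGA repeats (GAGAGAGA) stood at 1.53% against 1.71% (adjusted p = 0.632, Fisher's exact test). Motifs were counted on either strand and at any position in the window, so a match is not shown to be a working element. Base composition was not taken into account. The window lay at the outermost 5' end of a gene, whereas a peak counted at the 5' end of any transcript. Among 5 annotated tRNA pseudogenes 4 had a peak at the 5' end, and for 2 of them it was also the peak of a Pol III gene.

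In all, 24 peaks outside Pol III windows had a pooled signal at or above the median of the peaks at Pol III genes. Each was among the strongest of all 3 replicates. The intervals of 8 of them came within 100 bp of a snoRNA gene's 5' end, against 3 of the 2946 weaker ones. This pattern was noticed in these same peaks and not tested on others, and peak width was not taken into account. The summit lay at -19 bp at snoRNA:gcl-a and -17 bp at snoRNA:Me18S-A1806 (upstream negative). It lay farther off at snoRNA:Or-aca4 (-141 bp) and snoRNA:Psi28S-3342 (-232 bp), for example. The peak that reached snoRNA:Psi28S-2622 had its summit at -17 bp from sncRNA:CR43701. The tables argue against unannotated copies of tRNA genes as the source of the set, since 0% of the 24 (exact upper bound 14.2%) matched a tRNA gene in blastn within 200 bp of the summit, while the same search linked 99.1% of 229 peaks at tRNA genes to a tRNA gene elsewhere, and 54.6% to one of another amino acid family. They also argue against promoters of nearby protein-coding genes as the source of most of the set. Of these peaks 25% lay at such a 5' end, against 48.5% of the weaker ones (p = 0.0239, Fisher's exact test). Random placement of all optimal peaks gave 7.14%, so such promoters may account for some of the 24. An unannotated Pol III gene with a B box may account for some, but with a match at 12.5% of the peaks and 4.17% of the shifted regions (p = 0.609, Fisher's exact test) the number is too small to decide.

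Some of the genes counted here as Pol III genes had no peak, nor did the replication-dependent histone genes, which are protein-coding. Whether Pol III transcribes RNaseP:RNA, which is among them, was not examined. At 5S rRNA, 7SL and histone genes a median of 0% of the 32-base words within 200 bp of the 5' end occurred once in the genome, against 87.3% at tRNA genes with a peak, so reads shared between near-identical copies are a candidate explanation there (the read length is not given in the sources used here). Of the 21 tRNA genes without a peak, 95.2% had a B box match with at most 1 mismatch, and 69.9% of those with a peak (p = 0.0108, Fisher's exact test). The share was thus not lower without a peak. Matches differed between families, however: tRNA:Gln-CTG-2-2 and tRNA:Thr-AGT-1-1, for example, had a peak and no match. The contrast therefore cannot decide whether a degenerate B box plays a part. Shared reads stay open for the 21 genes without a peak. Their median of unique words was 86.8% (permutation p = 0.424). Still, 28.6% of them had under 50% unique words, against 1.12% of those with a peak (p = 5.06e-06, Fisher's exact test). Shared reads may account for that part. All words were unique at snRNA:7SKb, RNaseP:RNA, tRNA:Arg-TCT-2-1, tRNA:Arg-TCT-3-1 and tRNA:Cys-GCA-2-1, which also had no optimal peak. Exact repeats of 32 bases are therefore no candidate there. Copies that differ by single bases were not searched, and the read length and the filters are unknown.

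Peaks at protein-coding 5' ends made up the largest part of the set. The DNA replication-related element (TATCGATA), found at housekeeping promoters, lay within 100 bp of the 5' end in 11.2% of genes with a peak and 7.30% without (adjusted p = 3.61e-08, Fisher's exact test), so such promoters may account for some of these peaks, while most of the genes lack the element. Background at any promoter active in embryos stays open: patterning genes had a peak in 3.33% (exact interval 0.0844 to 17.2%; 6.67% ± 3.33 in the separate replicates, SD, n = 3) against 13.6% of other genes, a count too small to decide, and 50% of highly transcribed housekeeping genes had one.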
